A study of Homo sapiens with 14 samples.

How the data were processed

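MCF-7 cells, an established human breast cancer cell line that carries the oestrogen receptor, had been infected with a lentivirus that expressed a nonspecific short hairpin RNA (shNS) or one against RUNX1 (shRUNX1), per the labels' protocols. Infection was monitored by co-expressed GFP on day 2 and cells were selected with puromycin at 2 µg/ml. RNA-seq was done in 3 libraries of each kind. Hi-C, which counts ligated pairs of restriction fragments and so measures how often loci meet, was done in 2 samples of each kind. Wildtype cells gave 2 RUNX1 chromatin immunoprecipitation (ChIP-seq) libraries and 2 input libraries. Reads were 100 nt long. The labels number the replicates but do not say whether they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

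The submitters' processing notes name Bowtie, RSEM 1.2.7, DESeq2 and R 3.1.0 and the genome build hg19, without the role of each. The authors deposited RSEM expected counts per gene, estimated counts that need not be whole, for 25796 genes in 6 libraries; 9.61% of the values were not whole. The authors also deposited a table of log2 fold changes, shRUNX1 over shNS, with adjusted p-values. The deposited p-values have no stated filter or design, and the deposited log2 values were used only beside values computed here. The Hi-C matrices hold a contact signal which, per the file headers and names, was iteratively corrected in hg19 bins of 40 kb, 100 kb, 250 kb and 1 Mb. The values of the deposited contact signal showed that 40 kb and 100 kb maps had been corrected within each chromosome, and that 250 kb maps had been cut from a genome-wide correction. One map was given per condition, and whether it pools both replicates, the sequencing depth and the read filters are not given in the sources used here. The control map carries a name (shGFP) that no label uses and was taken as the nonspecific control because the labels hold only 2 Hi-C groups. The authors' peak list gives 3466 RUNX1 peaks with positions and no score or caller, so peaks could not be ranked or compared between replicates, and whether it pools both pulldowns is not given in the sources used here. Every per-sample column of the count table was matched to a label.

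Expected counts were rounded to whole numbers. Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with filterByExpr, TMM scaling, robust quasi-likelihood fits (glmQLFit, glmQLFTest) and Benjamini-Hochberg adjustment at 0.05, in a model with the 2 groups and no block. The filter kept 12979 genes; 6494 of the genes listed had no count in any library. CPM, counts scaled to the same library total, were computed from TMM-scaled library sizes, and standard errors (SE) were taken from the fold change and its F statistic. Totals ran from 4440196 to 9865774 expected counts per library. On simulated counts for these libraries (12799 genes kept), 80% of 2-fold changes and 16% of changes of 0.5 on the log2 scale were recovered, and 9.43% of calls were false. Pairs of libraries of a group differed by more than sampling noise, so none was counted as a copy of another. The chi-square per degree of freedom was 3.75 to 6.38 between shNS libraries. It was 27.6 and 25.75 between shRUNX1 replicate 1 and replicates 2 and 3, but 1.36 between replicates 2 and 3. Those 2 came close to sampling noise, so counts without shRUNX1 replicate 1 rest on 2 nearly alike libraries of that group. The main test also counts them as separate libraries, and if both came from 1 culture it overstates the replication. Gene lists (26) were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. Members were counted by the edgeR test over all genes and adjusted over the list alone.

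Named genes followed 1 rule. RUNX1 came first, then the 12 largest rises and the 12 largest falls among genes with adjusted p below 0.05, a mean of at least 5 CPM and no overlap between the groups, then up to 4 members of each list by adjusted p. Hi-C bins were named if they had the 5 largest rises or falls of compartment score among bins that changed sign, and boundaries if they had the 3 largest gains or losses of insulation score. Naming of peaks by score could not be done.

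Hi-C maps were analysed with Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3) over chromosomes 1 to 22 and X, in bins kept in both maps. Of the 250 kb bins 93.3% were kept in each map, of the 40 kb bins 92.2%. Compartment scores were the principal component of the correlation of observed over expected contacts, taken from the first 3 as the one that correlated most with RUNX1 peak density, oriented to be positive and scaled to an SD of 1; the shRUNX1 component was matched to the control score. Compartment strength was the mean observed over expected contact within the top and within the bottom 20% of bins by control score, over that between them. Insulation was the log2 mean contact in a 12-bin square (480 kb) across each 40 kb bin relative to the chromosome's median, where at least 75% of the square was kept, and boundaries were minima with a prominence of at least 0.2. Tests over positions used 1000 circular shifts of the peaks along each chromosome, two-sided, with the choice and orientation of the compartment component repeated in each shift. The smallest p that 1000 shifts can give is 0.001. Bins matched on compartment score were drawn from the same tier of scores on the same chromosome, 1000 times for peaks at boundaries and 200 times for pairs of bound bins. On a simulated chromosome of 600 bins, 100% of bins received the right compartment, 75.9% of planted boundaries were found within 1 bin and 29.0% of boundaries found were not planted. With no planted peaks, 5% of simulated runs passed 0.05, and with 10% of the peaks planted at boundaries 18% did. Between the maps no test over samples was possible, because each condition has 1 map. Spreads given for Hi-C values are over chromosomes. Shares of bins and boundaries carry 95% exact (Clopper-Pearson) limits only in judging alternatives.

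Alternatives covered the scaling, the tool, the count filter, a replicate block, leaving out each library, bin sizes, windows, thresholds, distances and orientations. Results that need gene positions in hg19 (peaks near promoters, peaks near changed genes, changed genes by compartment) were left out, because the gene table at hand is on another assembly (GRCh38.p14). It was used only for gene names and for gene order, in which 12755 of the 12979 tested genes (98.3%) were placed. Figures were drawn with matplotlib 3.10.9.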

Results

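RNA-seq libraries from MCF-7 cells with a nonspecific hairpin (shNS, n = 3) and from cells labelled shRUNX1 (n = 3) held totals of 6646620, 9865774 and 4440196 and of 7174759, 7712397 and 6963852 expected counts, respectively. Hi-C gave 1 contact map for each of these conditions from 2 labelled samples each, and RUNX1 ChIP-seq in wildtype MCF-7 cells gave 1 list of 3466 peaks beside 2 pulldown and 2 input samples. The series title names the question, which is whether RUNX1, a transcription factor of the core-binding factor family, takes part in chromosome folding and gene regulation in breast cancer cells. On the first principal component of log2 CPM, which held 72.7% of the variance, the shNS libraries lay between -39.8 and -38.8. The libraries labelled shRUNX1 lay at 20.8 (replicate 1), 48.6 (replicate 2) and 48.3 (replicate 3). Replicate 1 of this group also stood apart on the second component, at -38.7 against 13.6 and 12.9.

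The targeted gene was not lower in the libraries labelled shRUNX1. RUNX1 stood at 37.0 ± 2.17 CPM (SD, n = 3) with shNS and at 46.6 ± 4.80 CPM (SD, n = 3) in the libraries labelled shRUNX1, a log2 fold change of 0.33 (SE 0.108, edgeR adjusted p = 0.0360). The RUNX1 counts were 260, 350 and 167 in the shNS libraries and 303, 339 and 360 in the others. The authors' deposited table gave the same direction, a log2 fold change of 0.33 with an adjusted p of 0.0625. DESeq2 did not call the difference (adjusted p = 0.0677). With a library left out edgeR gave log2 fold changes from 0.25 to 0.39 and adjusted p from 0.000488 to 0.146, past 0.05 only when shRUNX1 replicate 1 was the one left out. The label was therefore not borne out by RUNX1 mRNA, and each direction below is that of the label. The files hold no protein measurement.

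**Figure D1:**
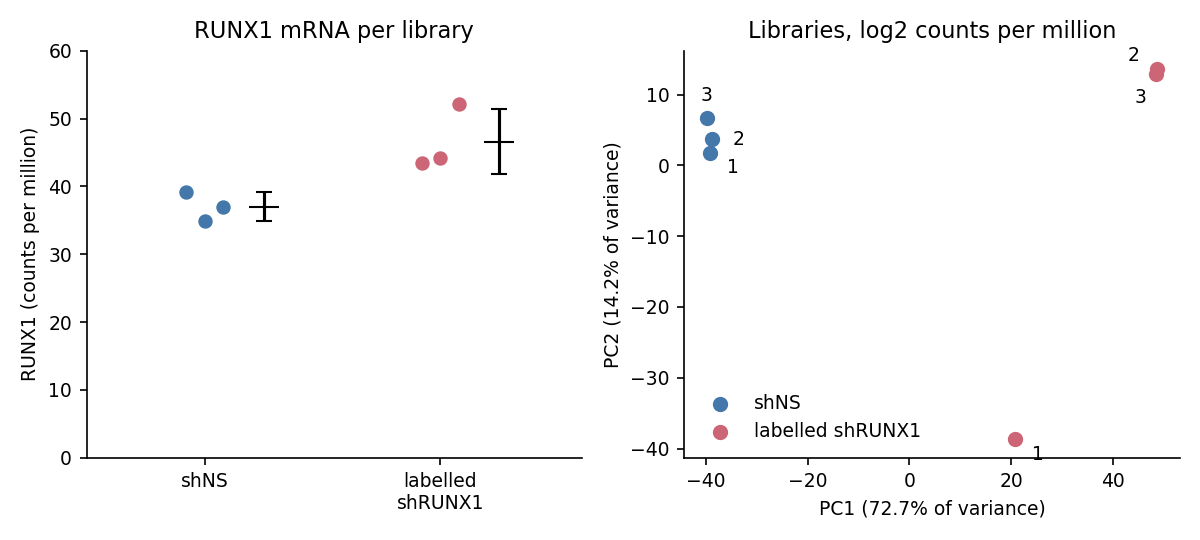
RUNX1 CPM in each RNA-seq library with the mean and SD of each group of 3 (left, linear axis from 0), and the libraries on the first 2 principal components of log2 CPM, numbered by replicate (right). All 3 libraries labelled shRUNX1 lie above the 3 shNS libraries in RUNX1, and shRUNX1 replicate 1 lies apart from replicates 2 and 3.

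Of 12979 genes, 2905 were higher and 2749 lower in the libraries labelled shRUNX1 (edgeR adjusted p below 0.05). Several of the 12 largest rises were genes of DNA replication and cell division. RRM2, the small subunit of ribonucleotide reductase, rose 10.5-fold from 17.6 ± 2.47 to 185.3 ± 7.11 CPM (SD, n = 3; adjusted p = 7.84e-06). MYBL2, a transcription factor of dividing cells, rose 10.6-fold, PRR11 8.52-fold, CDC25C, a phosphatase that starts mitosis, 8.50-fold, and SPC24, a kinetochore protein, 8.84-fold. Histone genes HIST1H2BB, HIST1H2BM and HIST1H3J rose 44.7-fold, 9.80-fold and 8.72-fold. The histone genes are near-identical copies, so reads may be split among them, and HIST1H2BB had 1 to 5 counts per shNS library. XIST, a long noncoding RNA, GALNT5, a glycosyltransferase, the interferon-induced IFI27 and NYNRIN completed the 12 largest rises, at 31.96-fold, 29.7-fold, 18.2-fold and 8.67-fold.

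The largest fall was that of CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, from 15.2 ± 0.879 to 0.235 ± 0.169 CPM (SD, n = 3; log2 fold change -5.93, SE 0.307, adjusted p = 1.50e-05), with 1 to 3 counts in each library labelled shRUNX1. The noncoding LINC01085 and PCSK2, a prohormone convertase, fell to 0.336 and 0.379 CPM from 16.3 and 15.6 CPM. With 0 to 5 counts of each in the libraries labelled shRUNX1, the order of CYP1A1, LINC01085 and PCSK2 is uncertain. Next in size were the following falls. MMP13 (collagenase 3) had a log2 fold change of -3.80, TNFRSF11B (osteoprotegerin) -3.32, MME (neprilysin) -3.24, TM4SF1 -3.20, CPXM2 -3.15, GJA1 (connexin 43) -3.14, SCIN -3.13 and SCNN1G, a subunit of the epithelial sodium channel, -3.01. RTEL1-TNFRSF6B, a readthrough gene that shares reads with its neighbours, had -3.22 and is uncertain, since DESeq2 gave it an adjusted p of 0.305. The number of genes past the threshold was 8513 without shRUNX1 replicate 1 and 3565 without shNS replicate 2. The 8513 rest on shRUNX1 replicates 2 and 3, which differed little beyond sampling noise. Scaling by the total count gave 2639 higher and 3038 lower, with the median over all genes at -0.0357 in place of -0.000314.

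Genes of the cell cycle rose almost as 1 block in the libraries labelled shRUNX1. In the G1/S and DNA replication list 39 of 40 genes rose and none fell, with the same counts adjusted over the list alone and a median log2 fold change of 1.35. TK1 (thymidine kinase), TYMS (thymidylate synthase) and the transcription factor E2F2 rose by 2.64 (SE 0.210), 1.56 (SE 0.131) and 2.29 (SE 0.144) on the log2 scale. In the G2/M and mitosis list 38 of 40 rose and none fell, also adjusted over the list alone, with a median of 2.07. Examples were ANLN, which builds the cleavage furrow (2.61, SE 0.117), the spindle motor KIF11 (1.68, SE 0.101), NUSAP1 (1.86, SE 0.120) and HMMR (2.24, SE 0.152). All 27 replication-dependent histone genes measured rose, adjusted over the list alone as well, with a median of 2.03. HIST1H3B rose 3.07, HIST1H3H 2.40, HIST1H3D 2.13 and HIST1H2BN 2.72 on the log2 scale. Camera adjusted p-values with the preset correlation were 1.79e-32, 1.10e-40 and 1.02e-58 for the 3 lists. With an estimated correlation none of the 9 lists called by camera passed, at adjusted p = 0.133 for G1/S, 0.133 for G2/M and 0.102 for the histones. Fry, which tests a list without setting it against other genes, gave the 3 lists unadjusted p = 0.000307, 0.000586 and 0.000112. Without shRUNX1 replicate 1, the library that stood apart, 39, 38 and 27 genes of the 3 lists rose and 1 G2/M gene fell.

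Targets of p53, the tumour suppressor that halts the cell cycle after damage, moved the other way. Of 29 measured p53 response genes 19 fell and none rose in the libraries labelled shRUNX1, with the same counts adjusted over the list alone and a median log2 fold change of -0.58. GDF15, a stress-induced secreted factor, went from 214.5 ± 7.85 to 58.7 CPM (log2 fold change -1.87, SE 0.0900, adjusted p = 1.08e-05). PLK2 had -1.40, the antiproliferative BTG2 -1.11 and the death receptor TNFRSF10B -0.88. MDM2 (-0.98) and CDKN1A (-0.53), the p53 ubiquitin ligase and the cyclin-dependent kinase inhibitor p21, were looked up after their values were seen. The camera adjusted p was 4.00e-08 with the preset correlation, and adjusted p = 0.102 with an estimated correlation. Without shRUNX1 replicate 1, 21 members fell and 2 rose.

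Metabolic genes rose in 2 lists. In the hypoxia and glycolysis list 18 of 30 genes rose and 3 fell (also adjusted over the list alone), with glycolytic enzymes among those that rose. LDHA, which makes lactate, went from 243.6 to 572.4 CPM (log2 fold change 1.23, SE 0.0782), PKM had 1.18 and ALDOA 1.05, while CA12, a carbonic anhydrase, fell from 367.8 to 164.9 CPM. The glucose transporter SLC2A1 (-0.36) and EGLN3 (-0.44), named after their values were seen, were the others that fell. In the cholesterol synthesis list 16 of 24 rose and none fell (also adjusted over the list alone), among them LSS (1.24), FDPS (70.6 to 161.9 CPM), MVD (1.32) and the receptor LDLR (0.87). Camera adjusted p-values were 6.01e-05 and 2.45e-07 with the preset correlation, and adjusted p = 0.102 and 0.151 with an estimated correlation. Without shRUNX1 replicate 1, 19 rose and 8 fell in the hypoxia and glycolysis list, and 18 rose and 1 fell in the cholesterol list. Cytoplasmic ribosomal protein genes rose in 28 of 50 cases and fell in 2, also adjusted over the list alone, with a median of 0.29. RPL13 had 0.79, RPL3 0.72, RPS15 0.86 and RPL14 0.64, and those that fell, named after their values were seen, were RPS24 (-0.22) and RPS25 (-0.36). The camera adjusted p of this list was 0.000181, and adjusted p = 0.538 with an estimated correlation. Without shRUNX1 replicate 1, 36 of these genes rose and 5 fell. Of 45 oxidative phosphorylation genes 16 rose and 8 fell, or 19 and 9 adjusted over the list alone, and the list was not called (adjusted p = 0.404). The counts were 26 and 10 without shRUNX1 replicate 1. SDHC and UQCRC1 rose by 0.85 and 1.07 on the log2 scale, and COX6A1 and NDUFA4 fell, at -0.55 and -0.57.

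Interferon response genes rose in 21 of 38 cases and fell in 5, or 22 and 6 adjusted over the list alone, with a median log2 fold change of 0.59. The transcription factor STAT1 had 0.73 (SE 0.0815), the double-stranded RNA sensor EIF2AK2 0.91, IFITM1 0.86 and LGALS3BP 0.69. The 5 that fell, named after their values were seen, were IFIT2 (-1.12), STAT2 (-0.47), IRF1 (-0.60), DDX58, the RNA sensor RIG-I (-0.60), and B2M, the light chain of class I antigens (-0.51). The list had a camera adjusted p of 0.00370, and adjusted p = 0.538 with an estimated correlation, and without shRUNX1 replicate 1 27 genes rose and 6 fell. IFI27 stood at 6.17 CPM in shRUNX1 replicate 1 and 30.1 and 28.8 CPM in replicates 2 and 3.

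Genes for chromatin architecture rose in 17 of 34 cases and fell in 6, or 18 and 7 adjusted over the list alone, in the libraries labelled shRUNX1. LMNB1 (lamin B1) went from 48.7 to 207.0 CPM (log2 fold change 2.08, SE 0.175), TMPO, a lamina-associated protein, had 1.04, NCAPG, a condensin subunit, 1.82 and CDCA5 (sororin), which holds sister chromatids together, 1.97. These 4 genes are also known to vary with the cell cycle. CTCF, the insulator protein, had 0.27 (SE 0.0818) and the cohesin loader NIPBL -0.28 (SE 0.0864), with edgeR adjusted p of 0.0291 and 0.0298, values looked up after the test. The camera adjusted p was 0.00151, and adjusted p = 0.102 with an estimated correlation. When shRUNX1 replicate 1 was left out, 19 rose and 11 fell. In the RUNX family and CBF complex list 7 of 18 rose and none fell, also adjusted over the list alone, and camera gave an adjusted p of 0.0560, while 12 rose without shRUNX1 replicate 1 and 5 with total-count scaling. Camera called this list with no filter on low counts (adjusted p = 0.0162) and without shNS replicate 3 (adjusted p = 0.0207), against adjusted p = 0.538 with an estimated correlation. The corepressor TLE4 had 2.62 (SE 0.284), the histone methyltransferase SUV39H1 0.94, the acetyltransferase EP300 0.75 and CBFB, the partner subunit of RUNX proteins, 0.43 (SE 0.0856).

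Genes of breast epithelial identity went both ways, and camera called none of their lists. Of 30 luminal genes 12 rose and 9 fell, with SPDEF (1.66), MUC1 (2.68), GRHL2 (0.76) and XBP1 (0.78) rising. The oestrogen response list had 17 risen and 10 fallen of 48, with PKIB (1.22), BLVRB (1.11) and FKBP5 (1.17) higher and CA12 (-1.16) lower. Of 18 basal and myoepithelial genes 7 rose, or 8 adjusted over the list alone, and 2 fell. ITGB4 (0.76), SFN (0.79) and TRIM29 (0.81) were higher and MME and, named after its value was seen, CDH3 (-0.54) lower. Of 16 mesenchymal genes 5 rose, including FN1 (34.1 to 90.4 CPM) and CDH11 (2.24 to 5.94 CPM), and 6 fell, including COL5A1 (-1.37) and TIMP3 (-2.19). The luminal, oestrogen response and mesenchymal counts were unaltered adjusted over the list alone. Without shRUNX1 replicate 1, 18 oestrogen response genes rose and 20 fell, and the counts were 14 and 11 (luminal), 10 and 5 (basal) and 6 and 8 (mesenchymal). The direction of camera then turned to lower for the oestrogen response (adjusted p = 0.693) and basal (adjusted p = 0.976) lists. The camera adjusted p-values with all libraries were 0.134 (luminal), 0.404 (oestrogen), 0.404 (basal) and 0.404 (mesenchymal).

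The remaining pathway lists were not called with all libraries either. Integrin and basement membrane genes had 3 risen and 6 fallen of 24, with ITGB6 (-1.60), ITGAV (-1.17) and COL4A5 (-1.33) lower. NOTCH targets had 3 risen and 3 fallen of 14, with NOTCH1 (-1.45) and JAG1 (-1.78) lower and NRARP (0.94) and DTX4 (1.16) higher. Of 14 NF-kB and inflammatory genes 5 fell and none rose, among them NFKBIA (-0.58), RELB (-1.57), CSF1 (-2.74) and IER3 (-0.84). In the TGF-beta list 8 rose and 6 fell of 28, with BMP7 (1.65) and ID1 (1.28) higher and TGFB2 (-1.45) and BAMBI (-0.70) lower. The Hippo and YAP list had 6 risen and 6 fallen of 21, or 7 and 7 adjusted over the list alone, with TEAD1 (0.71) and ANKRD1 (1.71) higher and NT5E (-1.23) lower. WNT genes had 6 risen and 3 fallen of 25, with FZD4 (0.74), GSK3B (0.63) and ZNRF3 (0.67) higher and DKK1 (-0.66) lower. Stress response genes had 8 risen and 6 fallen of 31, with PHGDH (2.76) and ASNS (1.67) higher and SLC3A2 (-0.63) lower. Immediate early genes had 4 risen and 6 fallen of 22, with EGR3 (1.85) higher and IER2 (-0.51) and IER5 (-0.75) lower. Except for the Hippo list, counts were the same adjusted over the list alone. Camera adjusted p-values were 0.184 (integrins), 0.343 (NOTCH), 0.0793 (NF-kB), 0.998 (TGF-beta), 0.630 (Hippo), 0.883 (WNT), 0.916 (stress response) and 0.805 (immediate early). More genes passed without shRUNX1 replicate 1, with 6 risen and 13 fallen (integrins), 5 and 6 (NOTCH), 2 and 6 (NF-kB), 11 and 8 (TGF-beta), 9 and 8 (Hippo), 7 and 7 (WNT), 11 and 11 (stress response) and 7 and 9 (immediate early). Camera called the NF-kB list without shRUNX1 replicate 2 (adjusted p = 0.0433), against adjusted p = 0.474 with an estimated correlation. DTX4 lost its call with some single libraries left out, with an adjusted p up to 0.1002 without shNS replicate 2. Markers of other cell types were scarce. Of 3 fibroblast genes measured COL1A1 rose and COL3A1 fell, at 8.22 and 1.21 CPM in the libraries labelled shRUNX1. Of 4 blood cell genes KIT rose and ITGAM fell, or 1 and 2 adjusted over the list alone, and the 1 endothelial gene, EMCN, fell. The calls of COL1A1, COL3A1, KIT and EMCN were not stable, with edgeR adjusted p up to 0.0906 without shNS replicate 1, 0.0869 without shNS replicate 2, 0.112 without shNS replicate 2 and 0.114 without shRUNX1 replicate 3, respectively. All 3 marker lists were not called by camera (adjusted p = 0.998, 0.445 and 0.542).

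**Figure D2:**
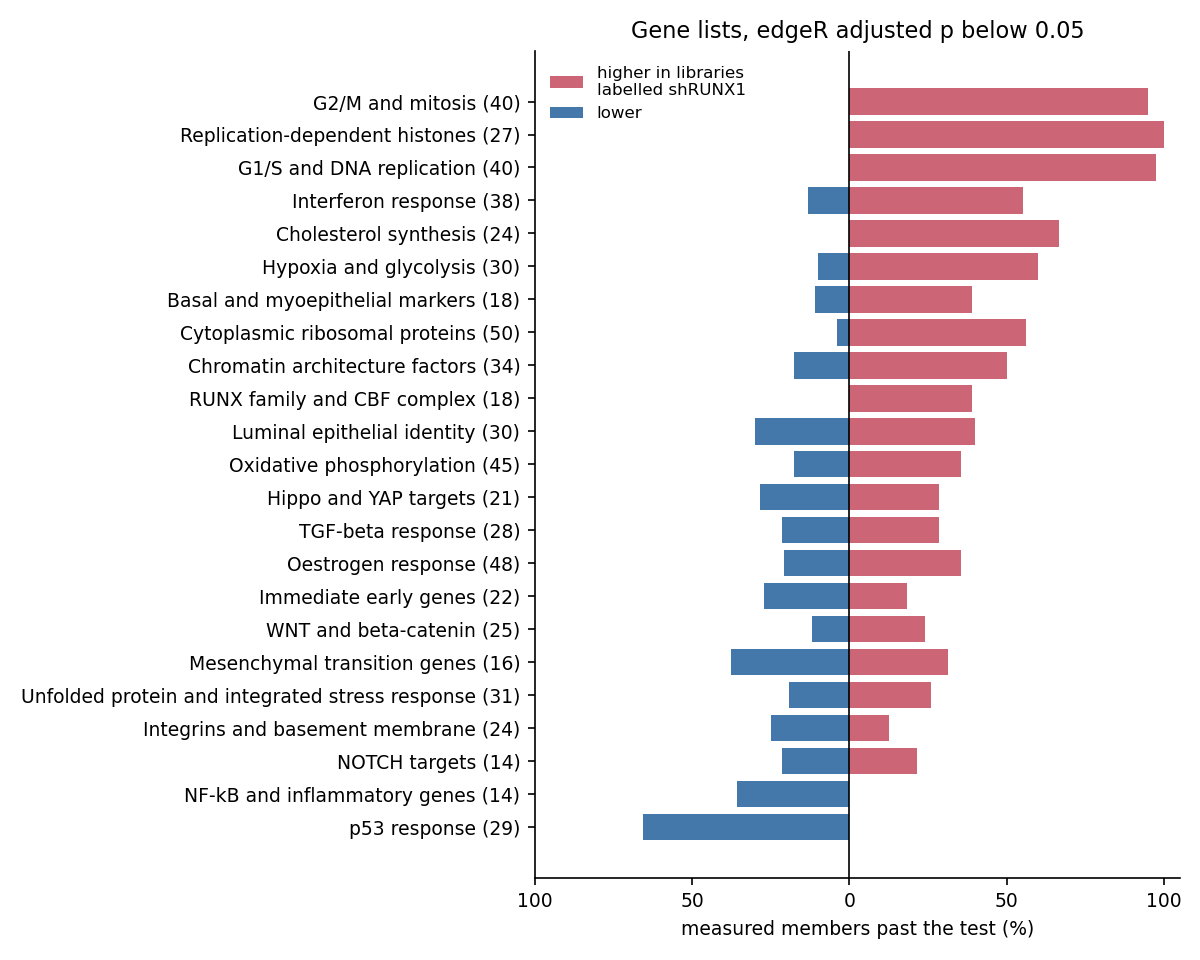
Percent of the measured members of each gene list (number measured in parentheses) that were higher (right) or lower (left) in the libraries labelled shRUNX1 than with shNS, edgeR adjusted p below 0.05, lists with at least 14 measured members, ordered by median log2 fold change. G2/M, histone and G1/S genes stand at the top with no member lower, and p53 response genes at the bottom with 19 of 29 lower and none higher.

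The authors' deposited table lists 2672 genes as higher and 2351 as lower at an adjusted p below 0.05. Across the 12979 genes tested here its log2 fold changes had a Pearson correlation of 0.987 with the edgeR values and 99.4% had the same sign, where genes are not independent replicates. Both tests called 4869 genes in the same direction. The series holds no other RNA-seq libraries, so the agreement shows only that the same comparison was made and is no independent support.

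RUNX1 peaks in wildtype cells were short, with a median width of 197 bp, and spread over all chromosomes at 1.14 per Mb (hg19). Chromosomes 16, 20, 17 and 19 held the most per Mb, at 2.56, 2.52, 2.34 and 2.27, and chromosomes 18, 13 and 4 the fewest, at 0.359, 0.425 and 0.434. The 1 Mb window with the most peaks lay on chromosome 16 from 85000001 to 86000000, with 19. Of the 3432 peaks in kept 250 kb bins, 84.4% (2895) lay in compartment A of the control map, the compartment of open, gene-rich chromatin, where 49.5% of bins are. Shifted peaks gave 61.2% on average, with 95% of shifts from 57.9% to 64.7% (circular shift permutation, two-sided p = 0.001, the smallest 1000 shifts can give). The shifted mean lies above 50% because each shift chose its own orientation. With the orientation taken from contacts between chromosomes, which uses no peaks, 83.5% of peaks lay in A against 50.3% after shifting.

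**Figure D3:**
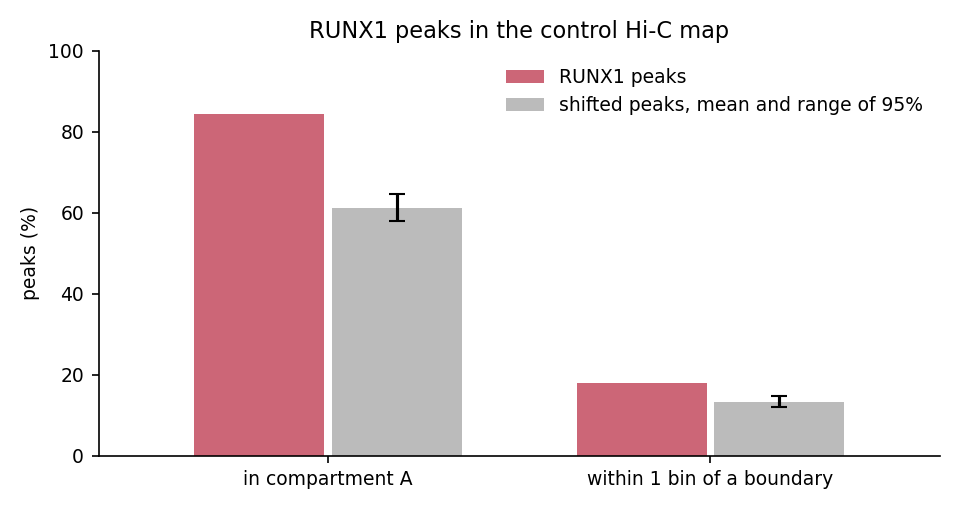
Percent of RUNX1 peaks in compartment A (250 kb bins) and within 1 bin (40 kb) of a domain boundary of the control Hi-C map, beside the mean of 1000 circular shifts with the range of 95% of shifts as error bars. Peaks exceed the shifted peaks in both, at 84.4% against 61.2% and 17.9% against 13.3%.

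Compartments were largely shared by the control and shRUNX1 maps. Scores of 11340 bins of 250 kb correlated at 0.956, and the median absolute change was 0.151 SD. The sign differed in 7.50% of bins, 449 from A to B and 401 from B to A, and 83.5% of these bins had a control score within 0.5 SD of zero. With both scores away from zero (above the 10th percentile of absolute scores) the share was 2.16%. Bins with a RUNX1 peak switched in 5.59% of cases and bins without one in 7.99%, a difference that was not tested. Chromosome 6 had 16.9% of its bins switched and a correlation between maps of 0.836, against 0.969 as the median over chromosomes. Chromosome 8 followed with 14.4%, and its score is less certain, being the only one taken from component 2, with a correlation of 0.377 with the track from contacts between chromosomes. The 5 largest falls among switching bins all lay near the end of the long arm of chromosome 6, starting at 156000001, 161250001, 163750001, 165500001 and 166000001, with changes of -1.81, -1.81, -1.94, -1.87 and -1.93 SD. These bins share 1 stretch and may hold 1 difference rather than 5 separate ones, which was not tested. Of 253 chromosome pairs in the 1 Mb maps, 6 and 14 changed most, from a log2 over expectation of 0.172 to 0.045. The largest rises were on chromosome 4 from 82500001 to 82750000 (1.69 SD) and from 83000001 to 83250000 (1.29 SD), on chromosome 21 from 17250001 (1.39 SD), on chromosome 8 from 130250001 (1.35 SD) and on chromosome X from 121000001 (1.33 SD). None of these 10 bins held a peak. Genes in these bins are not given, because no hg19 annotation was used.

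The contrast between compartments was lower in the shRUNX1 map when bins were sorted by the control score. The median strength over chromosomes was 3.003 in the control map and 2.72 in the shRUNX1 map, a log2 ratio of -0.13 (SD 0.0707 over 23 chromosomes), lower on 22 chromosomes and higher on 1. The drop was larger in 100 kb maps (-0.19) and with the top and bottom 10% of bins (-0.21), each lower on 22 chromosomes. The direction turned with the sorting. With both maps sorted by the shRUNX1 score the log2 ratio was 0.044, higher on 14 chromosomes, and with each map sorted by its own score it was -0.055, lower on 15.

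Domain boundaries, where the insulation score dips because few contacts cross, were mostly in place in both maps. Of 3029 control boundaries 75.2% had a boundary of the shRUNX1 map (2974 in all) within 1 bin, against 13.1% after shifting. Insulation scores correlated between the maps at 0.943 as the median over chromosomes, from 0.896 to 0.963. The control boundaries that lost most insulation, with contacts across them rising, lay on chromosome X from 3720001 to 3760000 (change 0.92), on chromosome X from 90840001 to 90880000 (0.75) and on chromosome 4 from 83200001 to 83240000 (0.75), inside a bin named above for its rise in compartment score. Those that gained most lay on chromosome 1 from 106720001 to 106760000 (-0.45), chromosome 4 from 65480001 to 65520000 (-0.41) and chromosome 6 from 155600001 to 155640000 (-0.40). None of these 6 had a RUNX1 peak within 1 bin.

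RUNX1 peaks lay at boundaries more often than shifted peaks. Of 3187 peaks in scored bins 17.9% lay within 1 bin of a control boundary, against 13.3% after shifting (95% of shifts from 12.05% to 14.7%, circular shift permutation p = 0.001, two-sided). Random bins of the same compartment score gave 13.99%, also with p = 0.001 over 1000 random draws (permutation). At the 466 control boundaries with a RUNX1 peak the insulation score rose by 0.088 (SD 0.128) from the control to the shRUNX1 map, and at the 2557 without one by 0.059 (SD 0.137). The difference of 0.028 lay outside 95% of shifts, from -0.017 to 0.012 (circular shift permutation p = 0.001, two-sided). At boundaries of the shRUNX1 map the means were 0.029 with a peak and -0.013 without, so the direction at unbound boundaries depended on the map they were taken from. With a 6-bin window the difference was 0.017 (permutation p = 0.017). It fell to 0.0044 (permutation p = 0.385) once insulation and compartment score were in a linear model.

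Contacts under 0.5 Mb took a larger share in the shRUNX1 map, with a median log2 ratio to the control of 0.062 (SD 0.0251 over chromosomes), higher on all 23 chromosomes. From 0.5 to 2 Mb contacts were lower on all 23, at -0.17 (SD 0.0377), and their median share of contacts within a chromosome was 13.2% in the control and 11.8% in the shRUNX1 map. From 2 to 10 Mb and from 10 to 50 Mb the log2 ratios were -0.025 (SD 0.0270) and -0.029 (SD 0.0492), lower on 20 and 17 of 23 chromosomes, and beyond 50 Mb -0.085 (SD 0.0751), lower on 19 of 21. When maps were scaled beyond 500 kb, 0.5 to 2 Mb contacts were still lower on all 23, at -0.091, while 2 to 10 Mb and 10 to 50 Mb turned to 0.051 and 0.043, higher on 22 and 19 of 23, and contacts beyond 50 Mb stood at -0.010, higher on 9 and lower on 12. In the 1 Mb maps 30.1% of the corrected signal lay within chromosomes in the control and 29.0% in the shRUNX1 map, lower on 18 of 23 chromosomes, with an SD of the change over chromosomes of 1.65 percentage points.

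**Figure D4:**
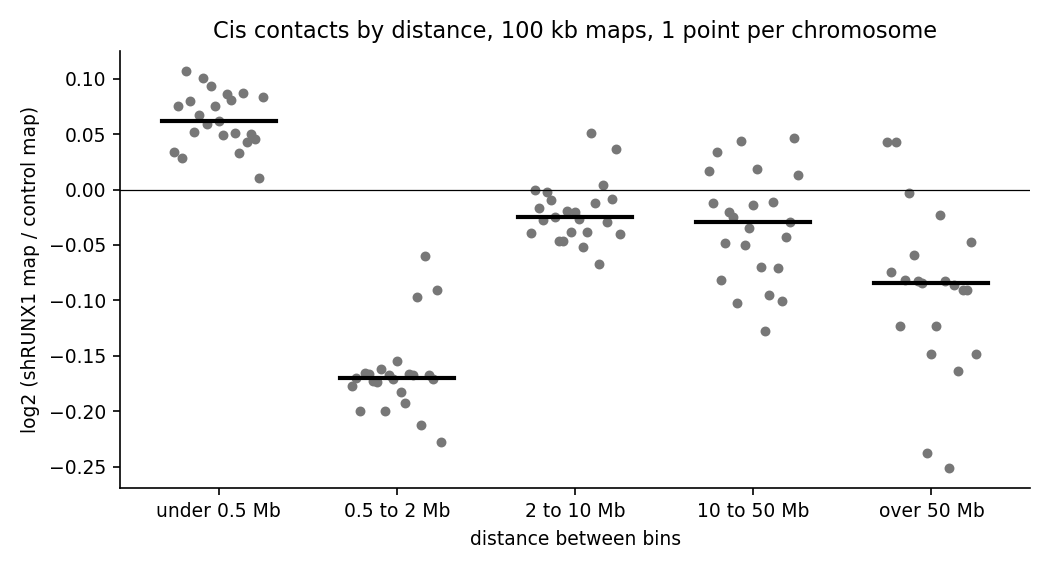
Log2 ratio of contacts within chromosomes, shRUNX1 map over control map, in 5 bands of distance, 1 point per chromosome in order from 1 to X and the median as a bar (100 kb maps, each chromosome scaled to the same total). All 23 chromosomes lie above 0 under 0.5 Mb and below 0 from 0.5 to 2 Mb.

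Pairs of RUNX1-bound 100 kb bins 0.5 to 10 Mb apart contacted each other at 1.19 times the expected signal in the control map and 1.21 times in the shRUNX1 map. The log2 ratio of 0.030 over 33311 pairs lay above 95% of shifts, from -0.017 to 0.018 (circular shift permutation p = 0.003, two-sided). The ratio was 0.068 in 250 kb maps (permutation p = 0.001) and 0.020 from 2 to 50 Mb (permutation p = 0.014). Random bins matched on compartment score had a ratio of 0.017, and the excess of bound bins over them, 0.012, did not pass (permutation p = 0.114).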

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

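Settings named here as total-count scaling, orientation by contacts between chromosomes, chromosomes with the first component in both maps, boundaries or scores of the shRUNX1 map, linear model and matched bins were chosen after seeing the data. The others were fixed before the data were examined. The main count of changed genes was 5654, and the others stayed within 1.5 times of it except with a log2 fold change of at least 1 (1487, fewer by construction) and when libraries were left out, from 3565 without shNS replicate 2 to 8513 without shRUNX1 replicate 1. Leaving out shRUNX1 replicate 1 lowers the spread of its group by construction, since the chi-square per degree of freedom of the remaining pair was 1.36. The cause of the other moves was not tested. The log2 fold change of RUNX1 stayed positive but lost its call with DESeq2 (0.34, adjusted p = 0.0677), total-count scaling (0.30, adjusted p = 0.0547) and the replicate block (0.33, adjusted p = 0.0558), and ran from 0.25 to 0.39 with libraries left out (adjusted p from 0.000488 to 0.146); the cause was not tested. The replicate numbers share only a number, with correlations of deviations of 0.061, -0.00719 and 0.0605 for replicates 1, 2 and 3, and replicate 2 did not correlate best with its own number; the block gave 5365 genes and 9 lists. Camera called 9 or 10 lists under every other setting and 0 with an estimated correlation. The added list was RUNX family with no filter and without shNS replicate 3, and NF-kB without shRUNX1 replicate 2. The estimate was 0.46 for G1/S, 0.55 for G2/M and 0.68 for the histones, far above the preset 0.01. Higher correlation alone cannot account for every lost call, however. For hypoxia and glycolysis the estimate was -0.033 and for chromatin architecture -0.019, both below the preset. The cause was not tested further. Fry gave the 9 lists unadjusted p from 1.19e-05 (hypoxia and glycolysis) to 0.0177 (interferon). It was also low for lists that camera did not call, such as the basal list (0.000398). The correlation with the authors' deposited table was 0.908 over all genes in both tables, which adds genes with low counts by construction. Of 117 named genes 6 lost their call under at least 1 alternative, 3 of them other than by leaving out a library, and COL6A3, not called in any setting, ran from -0.29 without shRUNX1 replicate 1 to 0.58 with libraries left out.

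Compartment switching was 8.16% at 100 kb (the cause was not tested) and 2.16% with low scores removed, which by construction drops bins near zero. It was 7.13% on chromosomes with the first component in both maps. Strength was -0.055 with each map sorted by its own score and 0.044 with the shRUNX1 score, as sorting by 1 map favours that map by construction. Shared boundaries were 73.3% (prominence 0.4), 73.6% and 72.4% (6-bin and 25-bin windows), by construction 46.7% (same bin) and 81.4% (within 2 bins); the cause was not tested for prominence and window. Scaling beyond 500 kb gave decay values of -0.091, 0.051, 0.043 and -0.010 for 0.5 to 2, 2 to 10, 10 to 50 and over 50 Mb, since by construction each band is then set against the others beyond 500 kb. The bound term fell to 0.0044 in the linear model, and the excess of bound bins to 0.012 against matched bins; the other settings for peaks, boundaries and bound bins kept direction and call, with sizes from 0.017 (6-bin) to 0.042 (boundaries of the shRUNX1 map) for bound boundaries and from 0.020 (2 to 50 Mb) to 0.068 (250 kb maps) for bound bins. Not run was the split of the peak list by score, which the list lacks, and the promoter, changed-gene and gene-compartment results, which need hg19 gene positions. Of simulated RNA changes of 0.5 on the log2 scale 16% were recovered, and whether depth or the spread between libraries sets this was not tested; Hi-C depth is unknown, and a median of 85.0% of cells were zero in the 40 kb control maps.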

Other observations

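The tests on copy number, on boundaries of the shRUNX1 map, on strength and compartment and on neighbouring genes were set down before their results were seen; the tests of scaling, exchanged libraries, exchanged labels, the library that stands apart, poly(A) tails, splits of libraries and mitotic cells only afterwards. Of 5 noncoding nuclear RNAs looked up, 4 were lower in the libraries labelled shRUNX1 and XIST, described above among the largest rises, was higher. They are no fixed list, and all genes of this paragraph were picked after their values were seen. MALAT1, a nuclear long noncoding RNA, went from 16316 ± 1726 to 4749 ± 1911 CPM (SD, n = 3; log2 fold change -1.78, edgeR adjusted p = 0.00101), and NEAT1, the scaffold of paraspeckles, had -2.01. RPPH1 and RMRP, the RNAs of ribonucleases P and MRP, had -0.59 and -0.92 (edgeR adjusted p = 0.0278 and 0.00470), and RPPH1 alone took 4.55% to 5.51% of counts with shNS and 2.77% to 4.18% in the libraries labelled shRUNX1. Of genes that follow the aryl hydrocarbon receptor, which were not tested as a list, AHRR, its repressor, had -2.49 and CYP1B1 -0.79, beside the fall of CYP1A1, while TIPARP had 0.13 (adjusted p = 0.613). In the 1 Mb maps 15 pairs among the small chromosomes 16, 17, 19, 20, 21 and 22 met above expectation in both maps, at a log2 of 0.40 in the control and 0.38 in the shRUNX1 map, a change of -0.024 (SD 0.0494 over pairs, 6 pairs higher), where the other pairs changed by 0.0033 on average. Every pair with chromosome 16 among the 15 was lower, from -0.122 (with 19) to -0.032 (with 20), and the 6 higher pairs were all without it. Chromosome 16 changed both ways with the larger chromosomes, by 0.115 with 13 and by -0.064 with 15. The mean is thus no even drop among small chromosomes.

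RUNX1 mRNA was not lower where the label says it was targeted. The RUNX1 log2 fold change stayed positive under 3 scalings. The lowest was 0.30 with total-count scaling, where the call was lost (edgeR adjusted p = 0.0547). The median of all genes lay between -0.0357 and 0.00473 under them, so they could hardly have brought RUNX1 to 0. They show only that the direction does not hang on the choice among these 3. An exchange of 2 libraries between the groups is argued against, as 0 libraries lay nearer to the other group on the first principal component. An exchange of all labels cannot be told apart from a knockdown that left the mRNA in place: RUNX1 was 20.5% lower in the shNS libraries, short of the 50% taken as what a knockdown would give, and no protein measurement is at hand. A rebound of RUNX1 mRNA in the selected cells stays open and untested.

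Cell cycle genes were higher in the libraries labelled shRUNX1. Without the library that stands apart, shRUNX1 replicate 1, 38 of 40 G2/M genes passed. That library lay at 20.8 on the first principal component, between the shNS libraries and the other libraries labelled shRUNX1. Leaving it out could therefore hardly lower the count, which shows only that the rise does not need that library. Copy number around these genes is argued against, since 154 nearest tested neighbours of 77 risen genes had a median log2 fold change of -0.0091 (95% bootstrap range -0.0914 to 0.129) against 1.67 for the genes themselves. More RNA without poly(A) tails could raise histone counts, but RPPH1 and RMRP, which lack such tails, averaged -0.75. A difference in growth state between the cultures, caused by the hairpin or by culture density, may fit and was not tested. Of the 10 splits of the 6 libraries, 1, the real one, gave 5654 genes and the highest of the others 0 (edgeR). Every other split put libraries of both groups on each side, so the group difference swelled its spread and made few calls likely. The 0 is thus no measure of chance, and 10 splits are too few for a share under 0.05.

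Contacts across RUNX1-bound boundaries rose more than across unbound ones. The choice of boundaries in the control map is argued against, since boundaries of the shRUNX1 map gave a larger difference, 0.042. The strength and compartment of bound boundaries may account for it, since the bound term was 0.0044 in a model that held both (95% of shifts from -0.017 to 0.012), against 0.028 without them. No effect of RUNX1 binding beyond position is therefore shown, and whether 1 map per condition would repeat is open.

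As a hypothesis, regional change of copy number or transcription between the cultures may contribute to the changed genes. Log2 fold changes of genes 10 tested genes apart correlated at 0.0619, above all 1000 shuffled orders (highest 0.0294, p = 0.001, the smallest these allow), and at 0.0441 without histone genes. Beside the histone cluster, 20 genes from PPP2R1A to ZNF525 had a median of 0.83 with 18 higher, and 20 from ZNF506 to ZNF724P 0.78 with 19 higher, against at most 0.745 in any window of 100 shuffled orders. The most lowered windows, from DNAJB2 to NYAP2 (-0.72) and from MARCH8 to CTGLF12P (-0.69), lay inside that limit. Zinc finger genes, a family of similar copies, stand at both ends of the window from ZNF506 to ZNF724P and at 1 end of that from PPP2R1A to ZNF525, so shared reads may also contribute and were not tested, and 0.0619 is a weak correlation. Another hypothesis was that more mitotic cells lowered contacts from 0.5 to 2 Mb. The rise of mitotic genes behind it was seen in the RNA libraries, and growth state was not measured in the separate Hi-C samples. Only insulation was set against this hypothesis, and contacts at other distances were not weighed. Mitosis erases boundaries, and the measures go apart. The insulation score varied more along the chromosome in the shRUNX1 map on 19 of 23 chromosomes, which goes against it. The mean score at the boundaries of each map was nearer to 0 in the shRUNX1 map on 21 of 23, which goes with it, so the explanation stays open.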
